A study of Homo sapiens with 2 samples.

How the data were processed

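The series holds 2 samples, 1 library each, of human neural stem cells grown from H9, an established human embryonic stem cell line. The sample named Og-NSC came from midbrain organoids, which are three-dimensional cultures steered towards midbrain tissue, and the sample named 2D-NSC came from a flat culture. Libraries were made with the 10x Genomics Single Cell 3' kit, per the labels' protocols, which tags each captured transcript with a unique molecular identifier (UMI) near its 3' end. Cell Ranger 2.1.1, Seurat 3.0 and the genome build hg19 are named in the submitters' processing notes, which do not say which step each served. The annotation release and the cell filter of the authors are not given in the sources used here.

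The authors deposited 1 matrix of raw UMI counts for 32738 genes and 25905 barcodes, with no normalization, together with a UMAP projection whose coordinates are scores without a unit. The deposited matrix pools both samples. Each barcode ends in a library suffix of 1 or 2, and nothing in the labels or the deposited data says which suffix belongs to which culture. No suffix was matched to a culture from its values, its order or its size. Nothing is therefore compared between Og-NSC and 2D-NSC: values are given for the suffix-1 library and the suffix-2 library as unassigned libraries, and for some genes over the whole matrix. The 2 coordinate columns of the deposited UMAP carry the names 2D and 3D and hold a value for every listed barcode, so they do not mark a culture. The 278 barcode sequences seen with both suffixes were treated as separate cells.

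Cells with at least 500 detected genes and a mitochondrial share of UMIs under 20% were kept, which removed 3 barcodes with suffix 1 and 1 with suffix 2. UMIs were summed over the cells of a library and expressed as counts-per-million values (CPM) of all UMIs. The log2 ratio of the libraries is always suffix 2 minus suffix 1, with an exact conditional Poisson interval at 95%. Shares of cells have exact Clopper-Pearson intervals at 95%. These intervals cover counting error only, whereas the intervals of list medians and of chromosome parts are bootstrap intervals over genes. With 1 library per culture and cells that are not replicates, no p-value or standard error is given, and a difference of these libraries has no replicate check. The median log2 ratio over the 14250 genes with 50 or more UMIs in each library was 0.12, so log2 ratios are reported relative to that median unless stated otherwise. In the count over all genes, a gene was past the 2-fold mark when it had at least 200 UMIs and 20 CPM in the higher library and its whole interval, before that shift was taken off, lay beyond 2-fold. For members of a gene list the same mark was used without these minimums, over members with 50 or more UMIs in both libraries together. The mark itself was set after the data were seen.

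A total of 35 gene lists of cell types, regions, signalling pathways and cell states, together with the rule for naming genes, was fixed before the data were examined. The rule took the 10 genes in each direction whose interval lay farthest from 0 among those with at least 200 UMIs and 20 CPM in the higher library, up to 4 members of each list with the most UMIs, and a fixed set of stem cell, midbrain and regional genes. Mitochondrially encoded, ribosomal protein, sex-linked marker and clone-named genes were left out of the ranking. A list's median over members with 50 or more UMIs was set against 10000 random lists of the same size matched on expression in 20 bins; its percentile describes these libraries and is not a test. SPON1, PECAM1, UHRF1 and CXCL8 of these lists were not analysed here, and some genes that the rule names are not reported here. Genes that share sequence with near-identical copies, such as NANOG and POU5F1 with their pseudogenes, are uncertain, because the treatment of shared reads is not given in the sources used here.

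Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on raw counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.5, without integration of the libraries. A cluster was called by a class name only with 3 or more class markers raised at least 1.5-fold over the other cells. After a first round of names went against leading genes, the rule was tightened with the data in view: a marker of the class had to be among the cluster's 10 leading genes or 50% of the class markers had to be raised, a non-neural class could have no neural or regional gene among those 10, and under 50% of the cells could carry a high doublet score. The 8 clusters left unnamed by this rule held 82.7% of the suffix-1 and 41.2% of the suffix-2 library. Cluster 8, with 0.39% and 28.0% of the libraries, met the rule for neural stem/progenitor cells but is given by number only, because genes of motile cilia are among its leading genes. Cluster 5, with 11.8% and 0.31%, met the rule for neurons with all 12 markers raised. It is also given by number only, because precursor genes are among its leading genes. Clusters 4 and 5 both have no neuron marker among their leading genes, but cluster 4 has no precursor gene there either. Doublet scores came from scrublet as run in scanpy with an expected share of 6%. It called 0 doublets in the suffix-1 library, where it did not work, and 8.90% of cells in the suffix-2 library, so called doublets were kept and leaving out the 8% highest scores of each library was added as an alternative. For comparisons of shares, each cell was also thinned to 2000 UMIs, which lost no cell. Cycling cells had a mean S or G2/M list score above that of 50 control genes per member matched in 25 expression bins.

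Chromosome membership and GC content came from GENCODE 29 by Ensembl gene identifier; hg19 annotation was not used here and no coordinates are printed. Each chromosome was divided at its widest gap between genes, which on chromosome 1 lies at the centromere. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

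The steps were tested on simulated data. With Poisson counts drawn for the suffix 2 over suffix 1 ratio, the interval covered the true ratio in 95.6% of 16305 genes. All 100 genes changed by a log2 of 1.5 and all 100 changed by 3 were past the 2-fold mark, and 0 of 5695 unchanged genes were. Such draws hold counting error only, so they check the calculation and not the rate of false calls between real libraries. Among 32 lists in unchanged simulated libraries the largest absolute median was 0.11. A simulated log2 difference of -0.32 for genes of 1q was found as -0.32. Alternatives covered scaling by median of ratios or without mitochondrially encoded and ribosomal protein genes, equal weight per cell, other cell filters, list minimums, cells outside the cycling calls, cluster settings, thinning and a minimum of 2 UMIs. Alternatives chosen after seeing the data were the barcodes of the deposited UMAP, the 8% highest doublet scores, cells of cluster 6 alone, genes of 1q left out and MKI67 or TOP2A UMIs in thinned cells.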

Results

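Single-cell transcriptomes were collected from H9-derived neural stem cells of a midbrain organoid culture and of a 2D culture, 1 library each. After filtering, 12163 cells of the suffix-1 library and 13738 of the suffix-2 library remained, 25901 in all. Over all 12166 and 13739 barcodes before filtering, the libraries held 75559905 and 96974553 UMIs, with a median of 5253.5 and 6062 UMIs and 2057 and 2353 detected genes per barcode. Median mitochondrial shares were 2.36% and 2.56%, and median ribosomal protein shares 25.2% and 21.9%. The study set out to characterise ventral midbrain stem cells from organoids beside those from 2D culture. Since the suffixes are not mapped to the cultures, the values below describe 2 unassigned libraries, and no statement about Og-NSC against 2D-NSC is made.

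The libraries held SOX2 and NES at like levels and differed in FABP7 and in which ventral and regional genes they carried. SOX2, a neural stem cell transcription factor, stood at 291 CPM in the suffix-1 and 281 CPM in the suffix-2 library, and NES, an intermediate filament of neural progenitors, at 130 and 140 CPM. FABP7, a fatty acid binding protein of radial glia, was higher in the suffix-2 library, at 2489 against 386 CPM. Of 12 neural stem/progenitor genes, 2 were past 2-fold higher in each library, and the list had a relative median of -0.02 at percentile 50.3. FOXA2, a transcription factor of the floor plate and of dopamine progenitors, was higher in the suffix-1 library, at 55.2 against 15.3 CPM. LMX1A, which specifies the midbrain floor plate with FOXA2, was higher in the suffix-2 library, at 105 against 48.9 CPM. Their log2 ratios relative to the all-gene median were -1.97 (-2.06 to -1.89) and 0.98 (0.93 to 1.03). Pooled over both libraries, SOX2 reached 286 CPM, LMX1A 80.4 CPM and FOXA2 32.8 CPM.

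Of 6419 genes deep enough to be counted, 229 were past 2-fold higher in the suffix-2 library and 288 in the suffix-1 library, and 62 and 104 were past 4-fold. With median-of-ratios scaling, which takes off the all-gene shift, the counts were 188 and 354. Among cells of cluster 6, which held 515 suffix-1 and 2176 suffix-2 cells, the counts were 58 and 53. There was no replicate check.

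The 10 genes standing farthest above in the suffix-1 library were led by CORIN, a serine protease used as a surface marker of floor plate cells, at 62.7 against 0.20 CPM. F13A1 followed with 34.7 against 0.13 CPM. COL3A1, a fibrillar collagen, reached 1630 against 14.0 CPM, a relative log2 ratio of -6.98 (-7.06 to -6.91). The others were IGFBP7-AS1, FAM19A1, the forebrain transcription factor SIX3 (22.6 against 0.31 CPM), F5, LPL, the matrix glycoprotein TNC (121 against 2.93 CPM) and CMTM8. IGFBP7-AS1 is an antisense gene at IGFBP7 and is uncertain, since the use of strand in counting is not given in the sources used here. In the suffix-2 library the list was led by PDYN, the precursor of dynorphin peptides, at 66.1 against 0.46 CPM. BARHL1 and BARHL2, homeodomain factors expressed among other places in the developing subthalamic region, reached 41.2 against 0.30 CPM and 43.5 against 0.66 CPM. SIM2, IRX3, VEPH1, CRH (607 against 38.6 CPM), RIT2 and the tachykinin precursor TAC1 (73.7 against 4.67 CPM) were also among its genes. The ratio of CRH turned among cells of cluster 6 alone, to a log2 of -0.13 before the shift.

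**Figure D1:**
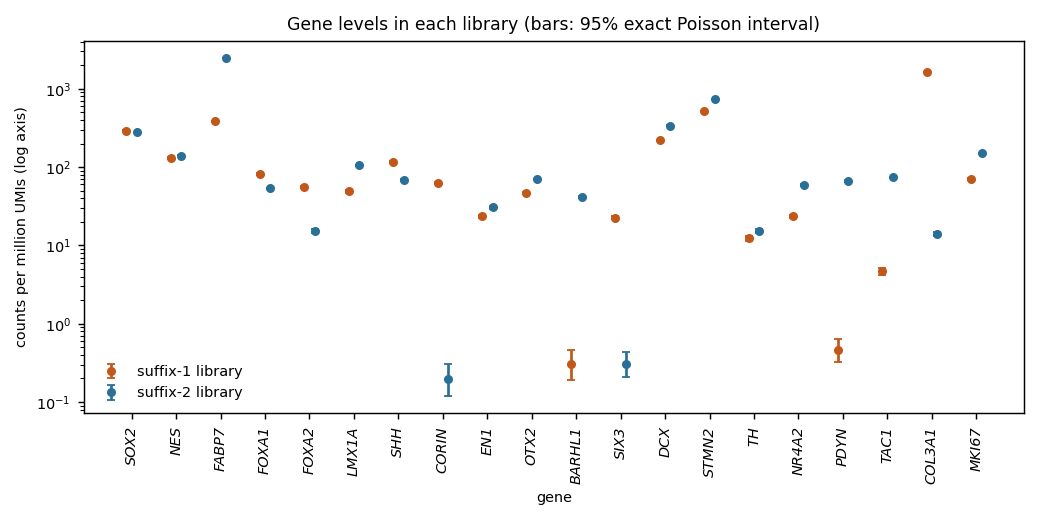
Level of 20 genes in each library, in CPM on a log axis, with exact Poisson intervals for counting error. SOX2 and NES lie close together in the suffix-1 and suffix-2 libraries, whereas CORIN (62.7 against 0.20 CPM) and BARHL1 (0.30 against 41.2 CPM) lie far apart in opposite directions.

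Genes of the midbrain floor plate did not move together. Of 9 measured members, 3 were past 2-fold higher in the suffix-2 library and 4 in the suffix-1 library; the relative median was -0.90, at percentile 0.03 of matched random lists. Beside CORIN and FOXA2, SHH, the floor plate morphogen, stood at 117 against 68.0 CPM in the suffix-1 library. FOXA1 was at 81.3 and 53.4 CPM. Among cells of cluster 6 alone the log2 ratio of SHH turned to 0.83 and the list median to 0.21, both before the shift; that median is over 6 measured members, without CORIN, which had 40 and 2 UMIs there, at 15.4 against 0.11 CPM. The midbrain regional list was at a relative median of 0.26 (percentile 94.4). Past 2-fold were 3 members higher in the suffix-2 library and 4 in the suffix-1 library, with 6 in neither. The 3 include BARHL1, described above for the subthalamic region, and LMX1A. LMX1A also counts in the floor plate list, and its log2 interval after the shift, 0.93 to 1.03, no longer lay wholly beyond 2-fold. EN1 and OTX2, which pattern the midbrain, were at 23.5 and 46.6 CPM in the suffix-1 and at 30.7 and 69.8 CPM in the suffix-2 library, and SPRY1 at 180 and 250 CPM.

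Forebrain genes were higher in the suffix-1 library, where 10 of 14 measured members were past 2-fold and 0 were in the other direction. Their relative median was -3.67, at percentile 0. FEZF1 stood at 14.3 against 0.60 CPM, DLX5 at 12.4 against 1.55 CPM and LHX9 at 13.7 against 3.07 CPM. Hindbrain and spinal genes were also higher in the suffix-1 library, in 4 of 5 measured members, with a relative median of -2.41 at percentile 0.05. GBX2 was at 16.3 against 3.34 CPM, while HOXB2 had 207 against 3 UMIs and HOXA2 1 against 0 UMIs. Among cells of cluster 6 alone, with 3 measured members each, the forebrain median was -2.09 (percentile 0) and the hindbrain and spinal median -0.85 (percentile 1.71). Over all cells they were -3.55 and -2.28, all before the shift.

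**Figure D2:**
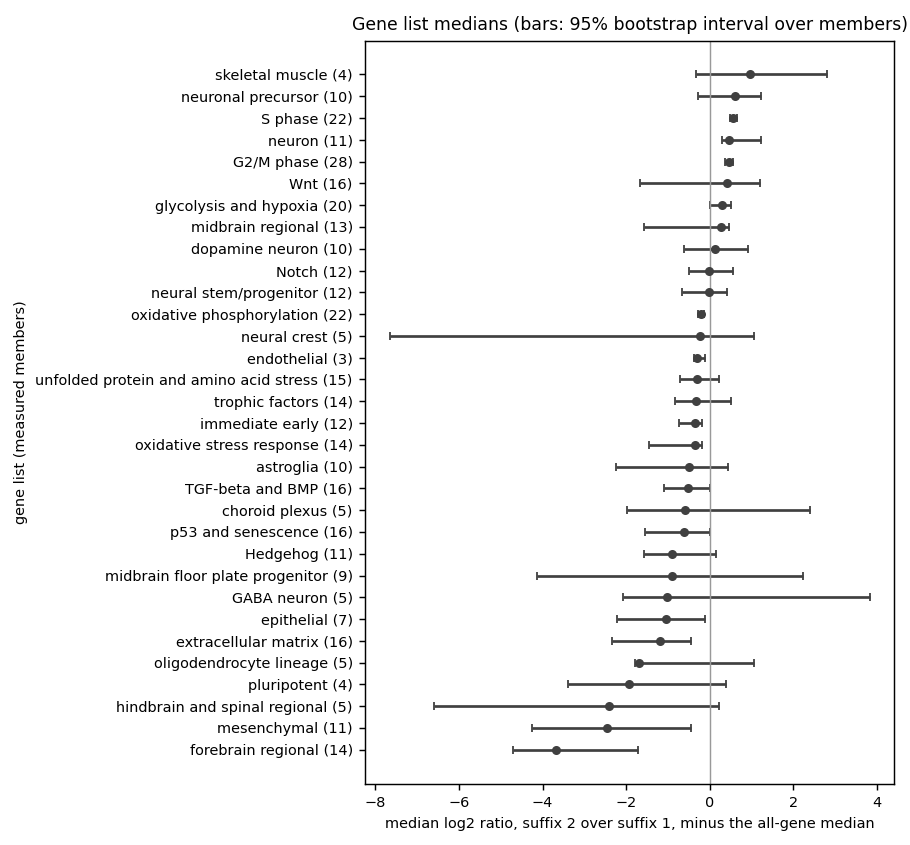
Median log2 ratio of each gene list, suffix 2 over suffix 1, minus the all-gene median, with bootstrap intervals over the members and the number of measured members in brackets. The forebrain list lies lowest at -3.67 and the skeletal muscle list highest at 0.97; 23 of 32 lists lay outside the central 95% of their random lists.

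LMX1A was detected in 23.4% (22.6 to 24.1) of suffix-1 cells and 46.5% (45.7 to 47.4) of suffix-2 cells. FOXA2 was detected in 26.0% (25.2 to 26.8) and 9.30% (8.81 to 9.79). After thinning to 2000 UMIs per cell, the shares were 9.76% and 18.9% for LMX1A and 10.0% and 2.80% for FOXA2. In the mesenchymal-like cluster 13 of the suffix-1 library, at a median of 5552.5 UMIs, LMX1A was detected in 11.1% and FOXA2 in 14.7% of cells, thinned 2.63% and 3.68%. These shares come from 190 cells of the suffix-1 library, which held more FOXA2 in all, at 55.2 against 15.3 CPM. They are therefore no background level for the suffix-2 library, where no cluster offered such a reference. Both transcripts were found in 7.92% of suffix-1 and 4.95% of suffix-2 cells, where independent detection would give 6.08% and 4.32%. After thinning these were 1.22% (1.03 to 1.43) and 0.59% (0.47 to 0.73), against 0.98% and 0.53%, so in the suffix-2 library the excess lay within counting error. Over 81 genes, mostly regional and neuronal and including genes of stem, cycling and mesenchymal cells, the intervals of 59 were apart at native depth; all of these kept their order after thinning, and all but FGF8, PITX3, SOX2 and WNT1 kept it with a minimum of 2 UMIs.

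The neuronal lists had higher medians in the suffix-2 library over all cells. The neuron list had a relative median of 0.45 (percentile 99.95), with 3 of 11 measured members past 2-fold, and the neuronal precursor list 0.60 (percentile 99.96), with 2 of 10 past 2-fold and 1 in the other direction. Among cells of cluster 6 alone both medians lay inside the central 95% of random lists, at 0.15 (percentile 72.7) and 0.33 (percentile 84.6) before the shift. DCX, a microtubule protein of young neurons, was at 219 and 338 CPM, STMN2 at 521 and 737 CPM, and the Notch ligand DLL1 at 8.56 and 32.6 CPM. The log2 ratio of STMN2 turned among cells of cluster 6 alone, to -0.25 before the shift. GAP43, at 428 and 473 CPM, had a relative ratio of 0.02 and turned there too, to -0.33 before the shift.

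Dopamine neuron genes were split, with a relative list median of 0.13 at percentile 78.3. TH, the rate-limiting enzyme of dopamine synthesis, was at 12.3 CPM in the suffix-1 and 15.3 CPM in the suffix-2 library, a relative log2 ratio of 0.19 (0.07 to 0.31). NR4A2, a transcription factor of dopamine neurons, was higher in the suffix-2 library, at 59.8 against 23.6 CPM, and KCNJ6, a potassium channel, at 59.0 against 5.07 CPM. DDC, which makes dopamine and serotonin from their precursors, was higher in the suffix-1 library, at 23.3 against 10.98 CPM, although its log2 ratio turned to 1.07 among cells of cluster 6, before the shift. TH was detected in 5.81% and 7.11% of cells, thinned 2.70% and 2.91%. In the mesenchymal-like cluster it was found in 3.68%, thinned 1.58%, which is a reference for the suffix-1 library only. SLC17A6, the vesicular glutamate transporter of midbrain and diencephalic neurons, was at 63.5 CPM in the suffix-2 and 4.06 CPM in the suffix-1 library. GAD2, an enzyme of GABA synthesis, was at 21.6 CPM in the suffix-1 and 5.61 CPM in the suffix-2 library. The GABA list had a relative median of -1.03 (percentile 1.56) with GATA2 in the other direction, at 10.5 CPM in the suffix-2 and 0.68 CPM in the suffix-1 library; its median turned to 0.44 among cells of cluster 6, before the shift and over 3 measured members instead of 5. The glutamate and serotonin lists had 2 measured members each and were given no median.

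Signalling genes divided as well. The Wnt list had a relative median of 0.41 (percentile 99.73), with 6 of 16 members past 2-fold higher in the suffix-2 library and 5 in the suffix-1 library. RSPO2, which amplifies Wnt signals, was at 421 against 74.6 CPM in the suffix-2 library, while DKK1 and SFRP1, secreted Wnt antagonists, were at 52.7 against 9.85 CPM and 50.4 against 17.1 CPM in the suffix-1 library. The Hedgehog list was at -0.90 (percentile 0.14), with HHIP at 17.4 CPM in the suffix-1 and 6.90 CPM in the suffix-2 library and PTCH1 at 14.0 and 16.2 CPM. Before the shift its median was -0.78. On that scale it was 0.13 over members with 500 or more UMIs, and 0.10 over the 8 members measured among cells of cluster 6. These alternatives lay at percentiles 52.5 and 50.2, so the list did not stand apart in either. The Notch list was at -0.01 (percentile 45.4), with 2 of 12 members past 2-fold, both higher in the suffix-2 library. TGF-beta and BMP genes were at -0.51 (percentile 0.31), with ID4 at 97.6 and 53.6 CPM; this median turned to 0.26 among cells of cluster 6, before the shift.

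The proliferation lists had higher medians in the suffix-2 library, though most members were not past 2-fold. The S phase list had a relative median of 0.54 and the G2/M list 0.45, both at percentile 100, with 0 of 22 and 3 of 28 members past 2-fold. MKI67, a nuclear protein of cycling cells, was at 150 against 70.2 CPM and TYMS, needed for DNA synthesis, at 87.5 against 42.9 CPM. Cycling scores were above control genes in 28.97% (28.2 to 29.8) of suffix-1 cells and 41.0% (40.2 to 41.8) of suffix-2 cells, and in 33.4% and 44.3% after thinning; 5.34% and 7.10% of cells lay within 0.02 of the limit. A UMI of MKI67 or TOP2A was found in 31.8% and 42.1%, thinned 18.3% and 24.8%. As background, MKI67 was detected in 6.28% of suffix-1 cells of the neuron-like cluster 4 and 8.99% of suffix-2 cells of the neuron-like cluster 11, at medians of 3413.5 and 4484 UMIs. Among cells of cluster 6 alone neither list stood apart: the S phase median was 0.19 (percentile 82.7) and the G2/M median -0.02 (percentile 12.2), before the shift.

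Matrix and mesenchymal genes were higher in the suffix-1 library. Of 11 mesenchymal members, 7 were past 2-fold and the relative median was -2.47; of 16 matrix genes, 8 were past 2-fold and the relative median was -1.20. Both lists were at percentile 0, and they share COL1A1, COL1A2 and COL3A1. COL1A1 was at 173 against 21.4 CPM and VCAN at 191 against 55.7 CPM. COL1A2 was at 602 against 479 CPM, SPARC at 345 against 337 CPM, and the log2 ratios of both turned among cells of cluster 6, to 0.19 and 0.18 before the shift. The list medians there were -0.87 over 10 mesenchymal and -0.94 over 15 matrix members, against -2.34 and -1.08 over all cells, all before the shift. Both lists stayed at percentile 0. COL3A1 was at 801 CPM in suffix-1 cells of cluster 6. COL3A1 UMIs were also found in 65.2% of cells of the neuron-like cluster 4, at 480 CPM. Free RNA from other cells of the suffix-1 library may therefore add to the cluster 6 medians, which was not tested.

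Clustering without integration of the libraries gave 14 clusters. Of these, 11, with 82.4% of all cells, drew at least 95% of their cells from 1 library. A cluster of that kind may be its library and not a cell type. The clusters are given with the genes that define them. The suffix-1 library held cluster 0 (F13A1, CORIN, COL3A1; 49.0% of its cells), cluster 1 (NEK2, KIF14, CDK1; 6.56%), cluster 2 (FGF19, SIX6, SIX3; 8.82%), cluster 3 (WIF1, DKK1, OTOR; 12.04%), the neuron-like cluster 4 (DLX5, DLX1, GAD1; 3.40%), cluster 5 (SCGN, LHX9, NEUROD1, DDC; 11.8%), and the mesenchymal-like cluster 13 (1.56%). The mesenchymal-like share of that library depended on the clustering, with 0% at a resolution of 0.3, 38.4% at 1.0 and 3.87% with 15 components. The suffix-2 library held cluster 7 (MKI67, TPX2, NDC80; 19.6%), cluster 8 (CRH, FABP7 and the motile cilium genes C1orf192, C9orf24, DNAH6 and C9orf171; 28.0%), the neuronal precursor-like cluster 9 (NHLH1, NEUROG2, DLL1; 8.92%), the neuron-like cluster 11 (TAC1, CHGA, SLC17A6; 21.4%) and cluster 12 (3.93%). Cluster 6 was defined by PAMR1, PMCH and EN1, and cluster 10 (GDF15, HMOX1, ATF3) had 142 suffix-1 and 154 suffix-2 cells. Clusters 4, 5 and 11 had neuron markers raised. They summed to 15.3% (14.6 to 15.9) of the suffix-1 and 21.8% (21.1 to 22.5) of the suffix-2 library. These sums are not compared, because precursor genes are among the leading genes of cluster 5. Clusters 4 and 5 both have no neuron marker among their leading genes. Of the dopamine list only DDC is among those of cluster 5, at 104 CPM, beside TPH1 at 301 CPM.

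Within these 3 clusters, TH was at 63.4 CPM in cluster 5, 28.6 CPM in cluster 4 and 41.3 CPM in cluster 11. NR4A2 was at 105, 13.2 and 187 CPM in the same order, and LMX1A at 80.2, 28.0 and 112 CPM. FOXA2 was at 66.9 CPM in cluster 5 and 4.64 CPM in cluster 11. FABP7 ranged from 147 to 613 CPM over the suffix-1 parts of clusters and from 872 to 4043 CPM over the suffix-2 parts with 90 or more cells. STMN2 was found in 65.3% to 73.1% of cells of clusters 0 to 3, 6 to 8 and 13, at 163 to 290 CPM, against 94.7% or more of cells in clusters 4, 5 and 11.

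**Figure D3:**
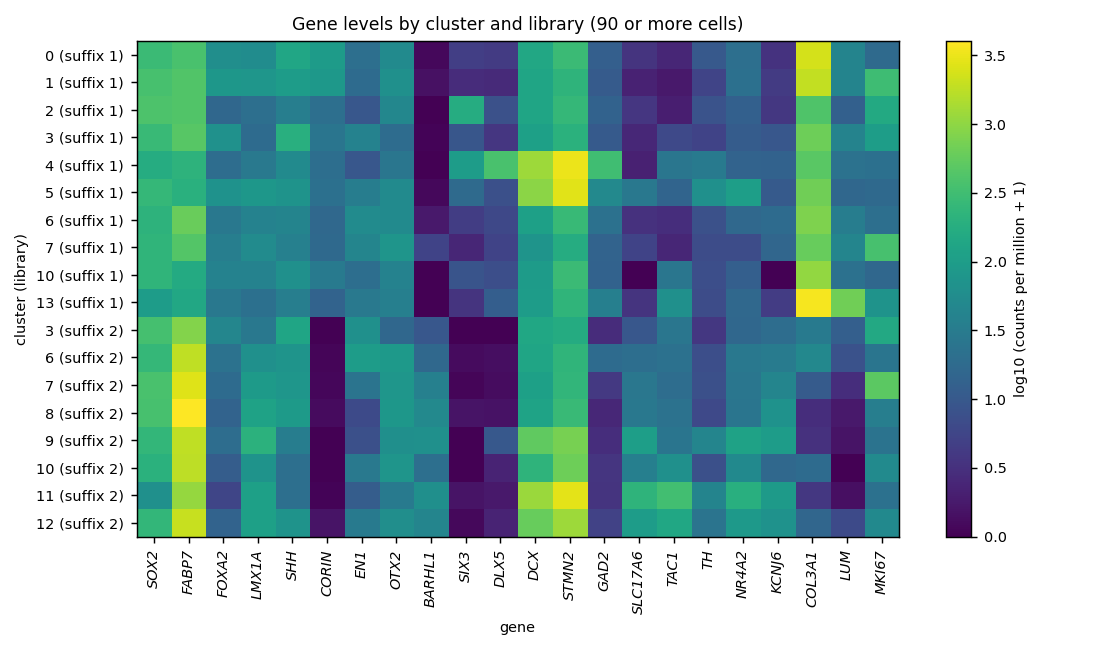
Level of 22 genes in each cluster, shown per library where that library has 90 or more cells, as log10 of CPM plus 1. STMN2 and DCX are high in clusters 4, 5 and 11, COL3A1 is above 400 CPM in every suffix-1 part and below 50 CPM in every suffix-2 part, and BARHL1 is at most 4.37 CPM in the suffix-1 parts.

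On the deposited UMAP, cells of the libraries lay closer together than in the clusters. Of the 15 nearest neighbours of a suffix-1 cell, 36.4% on average came from the suffix-2 library, which made up 52.99% of listed cells; for a suffix-2 cell 32.2% came from the suffix-1 library, which made up 47.0%. The suffix-2 cells nearest to cluster 4 were of cluster 11 in 88.3% of cases, and those nearest to cluster 5 of cluster 11 in 61.9% and of cluster 9 in 30.9%. Those nearest to cluster 0 were of cluster 6 in 68.9%, and those nearest to cluster 1 of cluster 7 in 96.9%. Of the neighbours of suffix-2 cells in cluster 8, 14.6% came from the suffix-1 library.

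**Figure D4:**
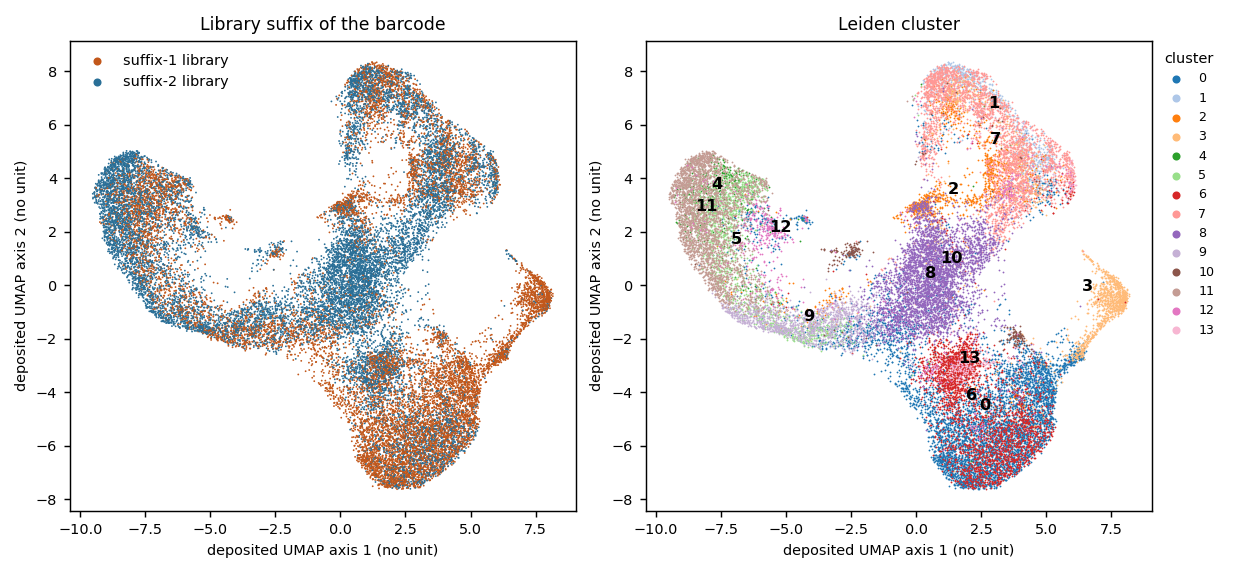
Deposited UMAP coordinates, without a unit, of the 25473 listed cells, by library suffix on the left and by cluster on the right. Clusters 4, 5 and 11 share 1 arm of the map although 96.96% of cluster 4 and 99.7% of cluster 11 came from different libraries.

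By chromosome, genes of 1q, the long arm of chromosome 1, stood apart. The median log2 ratio of 608 measured 1q genes was -0.28 (-0.33 to -0.24, bootstrap over genes) against all other genes, lower in the suffix-2 library. The other 40 chromosome parts lay between -0.10 and 0.18. Among the genes named here, F5, NES, LMX1A, MYOG, LHX9, CENPF, CKS1B and BTG2 lie on 1q.

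**Figure D5:**
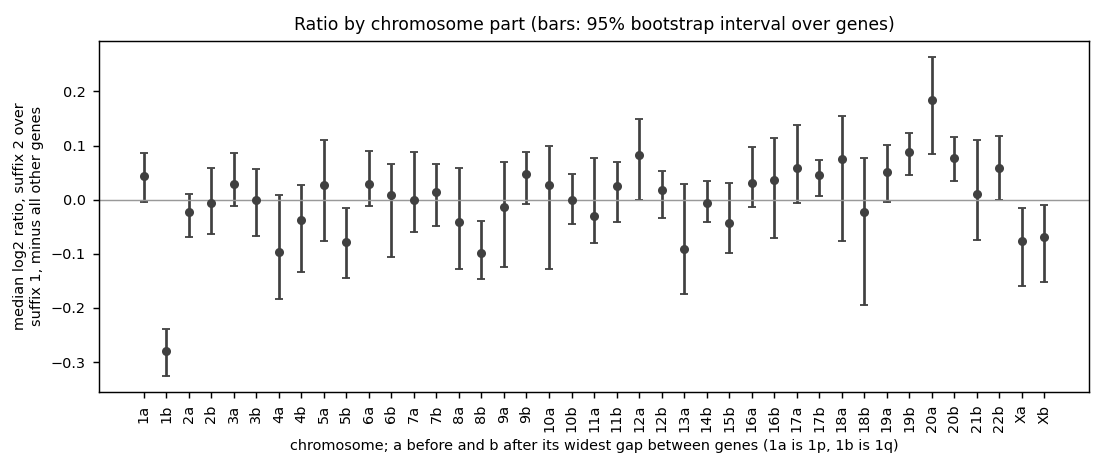
Median log2 ratio, suffix 2 over suffix 1, of the genes of each chromosome part minus that of all other genes, with bootstrap intervals over genes; a and b are the parts before and after the widest gap between genes. The part of 1q lies at -0.28 and all others between -0.10 and 0.18.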

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

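Values from cells of cluster 6 alone, from the barcodes of the deposited UMAP, from genes of 1q left out, from leaving out the 8% highest doublet scores and from MKI67 or TOP2A UMIs in thinned cells come from alternatives chosen after the result was seen; the other alternatives printed here were planned. No paired analysis was possible because each culture has 1 library and no barcode suffix is mapped to a culture. Depth limits genes near the floor, such as POU5F1 with 14 and 13 UMIs. Counts past 2-fold stayed between 188 and 247 (higher in the suffix-2 library) and between 262 and 377 (suffix-1 library) outside cluster 6. The part of them higher in the suffix-2 library was 44.3%, 34.7% with median-of-ratios scaling and 39.6% without mitochondrially encoded and ribosomal protein genes. Of the log2 ratios of named genes under all alternatives, 937 stayed within their counting interval, 344 moved beyond it and 17 reversed, where a reversal needs both intervals to exclude 0. Of the list medians, 101 stayed within the bootstrap interval of the list, 11 moved beyond it and 6 reversed, where a reversal is counted only for lists outside the central 95% of random lists over all cells. Among the other lists the sign also changed for choroid plexus (0.20, cluster 6), for neural stem/progenitor (-0.14), Notch (-0.02) and neural crest (0.06) in cells outside the cycling calls, against -0.48, 0.10, 0.11 and -0.12 over all cells, all before the shift. The cause of the changes below was not tested.

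Among cells of cluster 6 alone, which compares fewer cells and fewer cell types, 58 genes were past 2-fold higher in the suffix-2 library, 53 in the suffix-1 library, and 11 lists lay outside the central 95% of random lists. Ratios before the shift reversed there for CRH (-0.13), SOX2 (0.23), SHH (0.83), STMN2 (-0.25), GAP43 (-0.33), DDC (1.07), AQP4 (0.59), S100B (0.81), COL1A2 (0.19), KRT19 (-1.16), TTR (0.20), HEY1 (0.39), JAG1 (-0.58), ID1 (0.26), ID2 (0.77) and SPARC (0.18). List medians, over the members measured in that cluster, reversed for the floor plate (0.21), GABA (0.44), Hedgehog (0.10), TGF-beta and BMP (0.26) and G2/M (-0.020) lists. These reversed medians lay inside the central 95%, at percentiles 77.0, 82.6, 50.2, 90.9 and 12.2, so none stood apart in the opposite direction. Those of the neuron, neuronal precursor, S phase, p53, oxidative stress and unfolded protein lists also came to lie inside the central 95%. Trophic factors came to lie outside it (-0.40, percentile 0.56). With median-of-ratios scaling ATF4 reversed to -0.060. Over members with 500 or more UMIs the Hedgehog median reversed to 0.13, inside the central 95% (percentile 52.5). The unfolded protein list lay inside there too (percentile 5.38). In cells outside the cycling calls the TGF-beta and BMP list lay inside (percentile 3.84), and the dopamine (97.6), midbrain regional (98.5) and choroid plexus (2.39) lists lay outside.

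The share of cells in clusters that met the rule for neurons, which is not compared between libraries because precursor genes lead cluster 5, was, in the suffix-1 and suffix-2 libraries, 14.1% and 26.4% at a resolution of 0.3, 16.8% and 19.8% at 1.0, 12.5% and 26.1% with 15 components of 1000 variable genes, and 16.1% and 23.4% without the 8% highest doublet scores. The mesenchymal-like share was 0% in both libraries at 0.3, 38.4% and 6.81% at 1.0, where 6 clusters took the name, and 3.87% and 0.21% with 15 components. Without called doublets the share meeting the rule for neurons was 23.5% in the suffix-2 library, while the suffix-1 library had none called. The share of cells with a UMI fell, by construction, to 9.76% and 18.9% (LMX1A) and 10.0% and 2.80% (FOXA2) when thinned, and to 5.15% and 18.0% and to 6.19% and 1.17% with a minimum of 2 UMIs. Cycling shares were 33.4% and 44.3% when thinned, 31.8% and 42.1% by MKI67 or TOP2A UMIs, and 18.3% and 24.8% by these UMIs when thinned. For LMX1A, FOXA2 and cycling cells the order of the libraries was that of the report in each of these.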

Other observations

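The 6 tests that weigh explanations for 1q, COL3A1 and cluster 12 were chosen after the result was seen, whereas the gene lists were fixed before.

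Beyond neural genes, several cell state lists differed between the libraries. Of 16 measured p53 and senescence genes, 6 were past 2-fold higher in the suffix-1 library and 0 in the suffix-2 library, with a relative median of -0.63 at percentile 0.04. Before the shift the median was -0.50, against -0.23 over members with 500 or more UMIs and -0.005 (percentile 27.2) among cells of cluster 6 alone. CDKN2A, which codes for cell cycle inhibitors raised in senescent cells, stood at 55.1 against 2.01 CPM and CDKN2B at 51.8 against 11.6 CPM; both were chosen after their values were seen. CDKN1A, a p53 target, was at 39.1 and 36.5 CPM and BAX at 193 and 210 CPM. Glycolysis and hypoxia genes had a relative median of 0.29 at percentile 99.81, with 1 of 20 members past 2-fold: LDHA, which turns pyruvate into lactate, at 658 CPM in the suffix-2 and 261 CPM in the suffix-1 library. ENO1 was at 763 and 584 CPM and VEGFA at 22.2 and 31.5 CPM in the same order. Oxidative stress genes were at -0.35 (percentile 1.27), immediate early genes at -0.35 (percentile 2.01) and unfolded protein and amino acid stress genes at -0.30 (percentile 2.1); the first and last of these lay inside the central 95% among cells of cluster 6 alone, at percentiles 13.2 and 13.4. Oxidative phosphorylation genes were at -0.20 (percentile 12.1). Trophic factors were at -0.34 (percentile 8.21), with PTN, a growth factor of radial glia, at 401 CPM in the suffix-1 and 212 CPM in the suffix-2 library and MDK at 663 and 622 CPM.

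Other lists covered cells that such cultures can hold. Astroglial genes had a relative median of -0.50 (percentile 0.51), with AQP4, a water channel, at 95.5 CPM in the suffix-1 and 21.9 CPM in the suffix-2 library, though its ratio turned among cells of cluster 6, while GFAP had 12 and 23 UMIs. The oligodendrocyte list stood at -1.70 (percentile 0.29). Epithelial keratins KRT8 and KRT18 were at 41.9 and 50.4 CPM in the suffix-1 and 16.9 and 26.6 CPM in the suffix-2 library, and their list at -1.05 (percentile 0.51). Of the pluripotency genes, DPPA4 was at 12.6 CPM in the suffix-1 and 1.30 CPM in the suffix-2 library and DNMT3B at 4.65 and 6.61 CPM, while NANOG had 320 and 67 UMIs and POU5F1 14 and 13 UMIs over all cells; 4 were measured, with a median of -1.93 (percentile 0.34). The neural crest list was at -0.25 (percentile 30.7), with TFAP2B at 290 and 2 UMIs. Choroid plexus genes were at -0.61 (percentile 4.99), endothelial genes at -0.30 (percentile 25.1) and skeletal muscle genes at 0.97 (percentile 97.81, 4 members of at most 11.4 CPM), and 0 myeloid genes were measured.

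Genes of 1q were lower in the suffix-2 library by a median log2 of -0.28, a 1.21-fold difference, with 22 of 24 windows of 25 genes below the other chromosomes against 13 of 31 on 1p. A difference in cell composition as the whole cause is argued against by cluster 6, where cells of both libraries still differed by -0.31 (-0.35 to -0.26), and expression level or GC content by 10000 matched random lists, the lowest of which reached -0.089. For a difference in the copy number of 1q, the best step along chromosome 1 fell 44 genes from the centromeric gap, on the 1p side. That is past the 25 written down as the bound, so the prediction for this explanation was not met. It is also past 41 genes, the 95th percentile of 1000 steps simulated at the gap, of which 4.5% fell at least as far. The simulation shuffled the genes and so kept no runs of neighbouring genes with like ratios, which can move a step. The last full 1p window before the gap was at -0.31. The distance therefore does not decide whether a step lies at the gap. A breakpoint need not lie there, so the test cannot exclude a copy number difference, which stays open. Ratios between the libraries do not tell which of them would carry the change. Expression alone gives no karyotype, and whether the pattern follows the culture was not tested, since the suffixes are unassigned.

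COL3A1 UMIs in neuron-like cells of the suffix-1 library may be free RNA from other cells of that library. The level in cluster 4 was 20.6% of that in cluster 0, inside the middle 90% (15.6% to 73.4%, median 23.1%) of 35 other cluster 0 genes, those at 50 or more CPM and at least 20-fold lower in the neuron-like cluster 11 of the suffix-2 library. In cluster 5 the share was 28.3%, against a median of 24.1% (14.8% to 61.4%). The wide range leaves expression of some of these genes in the neuron-like cells open, and no biological explanation was tested.

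Cluster 12, with 540 suffix-2 cells and 1 suffix-1 cell, had genes of clusters 8 and 11 together and is consistent with doublets of neuron-like and cluster 8 cells. It had 0 genes of its own, against 22 to 246 in the other suffix-2 clusters, where a gene of its own had at least 50 CPM and lay over 1.5-fold above the highest other cluster. Its median of 9545.5 UMIs was close to the sum of clusters 8 and 11, 10271, and 83.2% of its cells had a high doublet score. Single neuron-like cells with more RNA are argued against by 86 genes of cluster 8, which lay at a median of 49.8% (44.0% to 55.1%) of the way from cluster 11 to cluster 8. Cells passing between the states of clusters 8 and 11 stay open, as no test of them was made.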
